A study of Mus musculus with 14 samples.

How the data were processed

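Small RNA was sequenced from 14 libraries of C57BL/6 mice, 2 for each of 7 cell groups. The groups were haematopoietic stem cells (HSC, named LSK in the deposited table), common myeloid progenitors (CMP), common lymphoid progenitors (CLP), common DC progenitors (CDP), splenic conventional dendritic cells (cDC), splenic plasmacytoid dendritic cells (pDC) and conventional dendritic cells grown from bone marrow with Flt3 ligand (Flt3L cDC). Per the labels' protocols, inserts of 19 to 24 nt were isolated on a gel, a preadenylated 3′ adaptor and then a barcoded 5′ adaptor were ligated, and the libraries were sequenced on an Illumina GAII. The labels give 4 barcodes. HSC and cDC carried the same one, CLP, pDC and Flt3L cDC shared another, and CMP and CDP each had their own, so barcode was fixed within a group and could not enter the model. The labels do not say whether the replicates of a group were separate animals, sorts or cultures, so every p-value measures only the spread between these libraries.

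The deposited table gave reads per 1000000 (RPM) for 1162 miRBase entries, of which 696 were mature or star sequences (named miR or let-7) and 466 were hairpins (named mir, in lower case). The column totals lay within 0.4 of 1000000 in the 8 progenitor libraries and fell short of it by 11.6 to 205 in the 6 DC libraries. The sources used here gave no reason for this difference, which goes with the contrast of DC and progenitors. The aligner, the miRBase release, the genome build and the rule that assigned reads to a hairpin entry were not given in the sources used here. Hairpin entries of some miRNAs with more than 1 genomic copy, such as mir-24, mir-26a and mir-3074, held nearly equal values, so calls on such copies are not separate observations. Identical values in all 14 libraries were held by miR-669p and miR-669a-5p, by miR-669o-3p and miR-669a-3p, by miR-466b-3p, miR-466c-3p and miR-466p-3p, by miR-466a-3p and miR-466e-3p, by miR-466b-5p and miR-466o-5p, and by miR-486 and miR-3107. Each was counted as an entry, so the 611 tested entries held 604 separate ones, and sums of the Sfmbt2 and red cell lists hold such reads more than once. Gene neighbourhood was read from an annotation of assembly GRCm38.p6, used for names and order alone.

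Low values in each library were whole multiples of the value of 1 read. Dividing by that value gave whole reads, within a tolerance of 0.1, for 99.5% of the nonzero values on average over the libraries, and for 97.6% in the library with the lowest share. The recovered reads served for depth, for the filter on low entries, for detection floors and for count-based alternatives. A floor of 3 reads over the libraries of a group was used wherever a group held no read. Such floors and counting intervals cover counting error alone, since amplified reads are not independent molecules. The depth of each library stands at the start of the results. A single read was worth 0.0680 RPM in the deepest library (pDC 1) and 23.5 RPM in the shallowest (CDP 2).

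The design was written before the data were examined and named edgeR's quasi-likelihood test for raw counts and limma for normalized values. Because the deposited unit was RPM, the limma branch applied. Entries were kept by edgeR's filterByExpr on recovered reads, which left 611 entries (401 mature or star and 210 hairpin) holding 99.9% of the reads and corresponded to about 9.84 RPM in at least 2 libraries. limma with an intensity trend was fitted to log2(RPM + 1) with 1 mean per group and all 14 libraries, which left 7 residual degrees of freedom and a prior of 9.65. The median residual SD was 1.26 on the log2 scale. Fold changes use log2(RPM + 1), which understates change in low entries and can overstate it in groups without reads. P-values were adjusted with the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a call. A comparison of splenic DC with progenitors set the mean of cDC and pDC against the mean of HSC, CMP, CLP and CDP. There were 8 pairwise contrasts besides, and 1 F test over all 7 groups.

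The design also fixed 20 lists of miRNAs. These were HSC-enriched miRNAs, the Hox-embedded miR-10/196 miRNAs, the Dlk1-Dio3 imprinted cluster, the miR-17/92 and paralogue clusters, the let-7 family, the miR-23/27/24 clusters, the miR-15/16, miR-29, miR-30 and miR-181 families, the miR-221/222 and miR-183/96/182 clusters, myeloid and DC miRNAs, lymphocyte miRNAs, the Sfmbt2 intronic cluster, and markers of red cells, of stroma and muscle, of endothelium and platelets, of epithelium, and of liver and brain. Several lists share members, not all named here: miR-342 (myeloid and lymphocyte), miR-155 (myeloid and HSC-enriched), and miR-181a and miR-181b (lymphocyte and their own family). Others, such as miR-10a, stand in the HSC-enriched and Hox-embedded lists. miR-126 stands in the HSC-enriched list and makes up the endothelial and platelet list. Calls on lists that share members are not separate observations. Each list was tested with camera at a preset correlation of 0.01 between miRNAs, adjusted over the 20 lists of a comparison, and again with an estimated correlation. The test camera compares the members of a list with all other tested entries, so a list called higher or lower is so relative to them. The median log2 change of all entries was -0.69 for splenic DC against progenitors and between -0.73 and 0.12 in the pairwise comparisons. The test fry, which asks whether the members of a list changed by themselves, was also run, and its p-values are unadjusted. Member counts are given for calls adjusted over all 611 entries and for calls adjusted over the list alone.

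The rule for named miRNAs was also fixed before the data were examined. Per comparison it took, among calls whose higher group had a mean of at least 100 RPM and whose libraries did not overlap between the sides, up to 10 of the largest positive and 10 of the largest negative fold changes. It further took the called members of each list, up to 4 members of highest mean per list, and the 5 most abundant entries per group. Values are given as mean ± SD in RPM over the libraries of a group, and fold changes as log2 ± SE.

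The procedure was tested on simulated reads drawn from the means and depths of these libraries. The simulated SD was 0.998 on the log2 scale in every comparison, below the median residual SD of 1.26. Replicates also differed in spread by group, with a median absolute log2 difference of 0.165 in CLP and 2.39 in pDC. The shares recovered and the counts of unchanged entries called may therefore be too favourable for these data. For splenic DC against progenitors (598 entries tested), 88.5% of the 8-fold and 99.0% of the 32-fold changes were recovered, and 4 of 400 unchanged entries were called. For cDC against CDP (607 entries), these shares were 45.0% and 86.0%, with 17 of 407 unchanged entries called. For CMP against HSC (602 entries) they were 31.1% and 80.0%, with 3 of 404, and for pDC against cDC (583 entries) 56.0% and 82.6%, with 2 of 391. In these simulations the changed entries left the total of the library as it was. When they were allowed to shift it, 205 of 374 unchanged entries were called for splenic DC against progenitors, because RPM values are shares of a total. The counts were 35 of 381 for cDC against CDP, 12 of 383 for CMP against HSC and 47 of 388 for pDC against cDC. For splenic DC against progenitors 52.6% of the 8-fold changes were then recovered.

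Alternatives written before the data were examined were quantile normalization, no filter, a filter of 100 RPM in at least 1 group, pseudocounts of 0.1 and 10, the replicate number as a block, a fit on the compared groups alone, removal of red cell miRNAs, contrasts within shared barcodes, omission of each library in turn, and camera with an estimated correlation. TMM scaling, RLE scaling, edgeR's quasi-likelihood test and DESeq2's Wald test on the recovered reads, mature entries alone, the CLP libraries counted as 1, and a filter at 1 read of the shallowest library were added after seeing the data. Each was applied to the counts of calls, to the named miRNAs with the largest changes and, where the method allows, to the list tests. No library and no column was left out. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.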

Results

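MicroRNA levels were measured by small RNA sequencing in 7 cell groups that follow the development of dendritic cells (DC), with 2 libraries per group. Bone marrow freed of cells bearing Gr-1, CD19, Ter-119, Mac1, CD8 or CD3 gave HSC (c-Kit+ Sca-1+ Flt3R-), CMP (labelled c-Kit- Sca-1+ FcR- CD34+, where CMP are usually sorted as c-Kit+ Sca-1-), CLP (c-Kit intermediate, IL7R+ Flt3R+) and CDP (c-Kit intermediate, M-CSFR+ Flt3R+). Collagenase-digested spleen gave cDC (CD11c+ CD4+ SiglecH-) and pDC (CD11c intermediate, SiglecH+ CD11b-). Flt3L cDC carried the same gate as cDC and came from whole bone marrow kept for 8 days with 200 ng/mL of Flt3 ligand. Replicates 1 and 2 held 2353208 and 2817335 reads in HSC, 2587598 and 528915 in CMP, 618174 and 216534 in CLP, and 113821 and 42498 in CDP. They held 339897 and 1480707 in cDC, 14707340 and 12064898 in pDC, and 212340 and 1415065 in Flt3L cDC. The number of miRNA entries with a read went from 410 in CDP 2 to 1039 in pDC 1, and a group without any read of an entry could hold up to 19.2 RPM of it in CDP but 0.112 RPM in pDC.

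**Figure D1:**
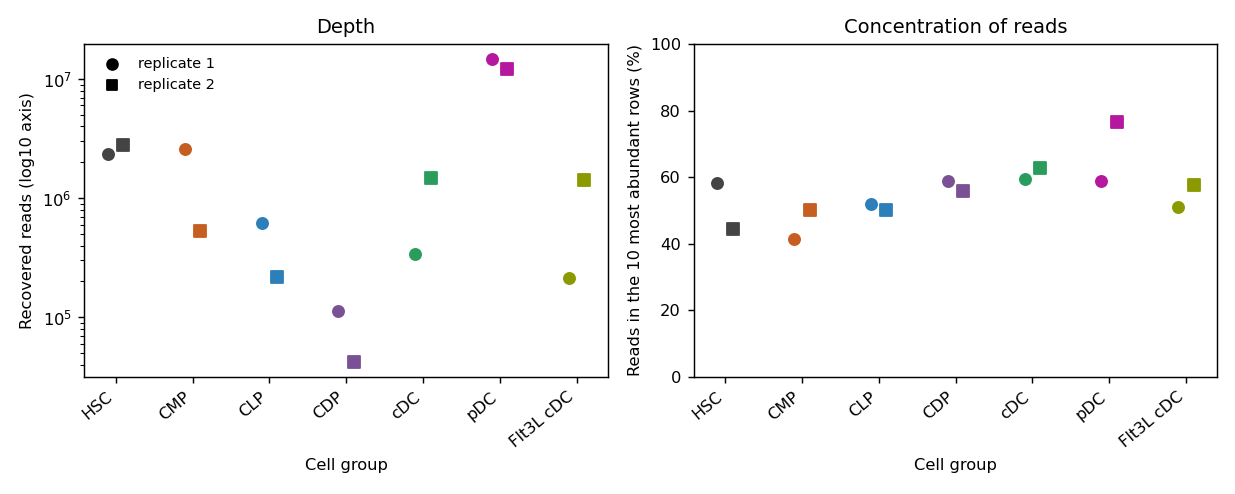
Left, recovered reads per library on a log10 axis, and right, the percentage of reads in the 10 most abundant entries, by cell group (circles, replicate 1; squares, replicate 2). Depth went from 42498 reads (CDP 2) to 14707340 (pDC 1), and the 10 most abundant entries held 41.4% (CMP 1) to 76.7% (pDC 2) of the reads.

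The 10 most abundant entries held 41.4% to 76.7% of the reads of a library. miR-16, which targets cell cycle and survival genes, led in HSC (159744 ± 128510.0 RPM, mean ± SD, n = 2), CLP (89176 ± 3537), CDP (195044 ± 27919), cDC (200496 ± 47614), pDC (152107 ± 32492) and Flt3L cDC (84333 ± 6865). In CMP, miR-106b led with 91045 ± 44152 RPM, ahead of miR-16 with 56594 ± 3052. HSC were also rich in miR-93 (45698 ± 21926 RPM), miR-181a (43813 ± 22601), miR-20a (36870.2 ± 9509.9) and miR-106b (35784 ± 6189.9). CMP carried miR-26a (41264 ± 13532), miR-181a (37596 ± 21286) and let-7a (36886 ± 7362). The other leading entries of CLP were let-7a (83813 ± 5998), let-7c (62822 ± 5461), let-7f (47826 ± 2611) and miR-181a (45802 ± 1252). In CDP they were miR-15b (89426 ± 1883), miR-181a (48314 ± 11073), miR-15a (45701 ± 8446) and miR-106b (40813 ± 2713). Splenic cDC held let-7f at 57692 ± 39018 RPM, miR-15a at 55199 ± 18106, let-7a at 49698 ± 1945 and miR-26a at 49043 ± 4445. In pDC, miR-181a reached 130722 ± 162649 RPM with a wide spread between the 2 libraries. It was followed by let-7a (82479.8 ± 51366), let-7f (47185 ± 35021) and miR-26a (44056 ± 10808). Flt3L cDC had nearly as much miR-22 (83307 ± 47067 RPM) as miR-16, then miR-181a (77358 ± 63522), let-7a (59773 ± 12088) and miR-26a (52332 ± 3288).

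miR-106b lies next to miR-93 and miR-25 in the annotation of assembly GRCm38.p6, yet its level varied against that of miR-93. The ratio of miR-106b to miR-93 lay between 0.440 and 6.33 in the 8 libraries of HSC, CMP, CDP and cDC, with a median of 1.69. In the 6 libraries of CLP, pDC and Flt3L cDC, which share a barcode, the median was 0.135. Of these, pDC 1 stood at 3.79 and the other 5 between 0.0303 and 0.147. The ratio of the partner strand miR-106b* to miR-93 had medians of 0.0171 and 0.0136 in these sets of libraries. These values stand beside every level of miR-106b given here.

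**Figure D2:**
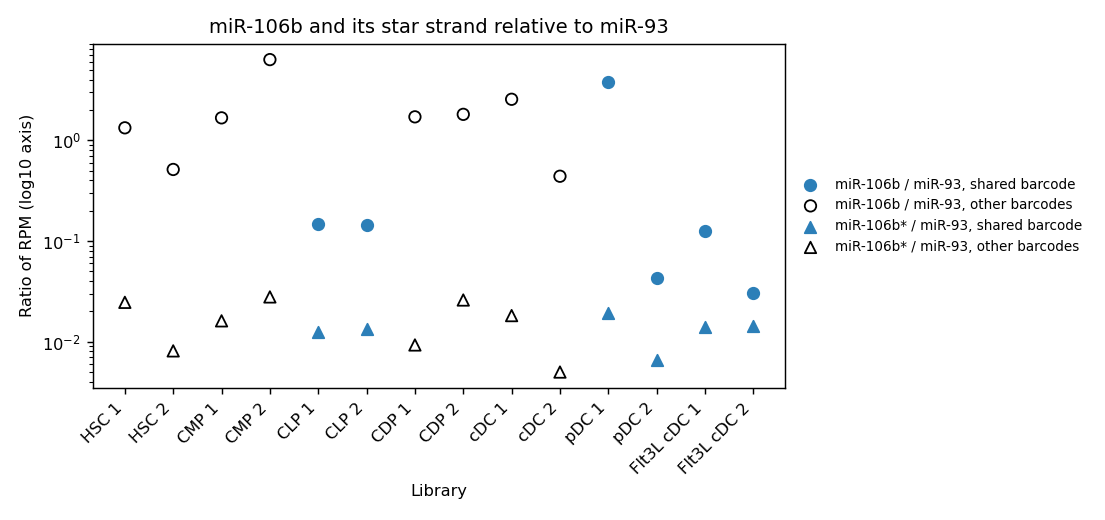
Ratio of miR-106b (circles) and of miR-106b* (triangles) to miR-93 in each library on a log10 axis; filled symbols are libraries of the barcode shared by CLP, pDC and Flt3L cDC. The circles of that barcode lie at 0.0303 to 0.147 except pDC 1 at 3.79, and those of other barcodes at 0.440 to 6.33.

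The first comparison asked which miRNAs separate mature splenic DC from marrow progenitors. miR-196b, encoded in a Hox cluster, fell from 5042 ± 6058 RPM in the 8 progenitor libraries to 16.3 ± 12.9 RPM in the 4 DC libraries, a log2 change of -7.30 ± 0.68 (limma, adjusted p = 2.07e-06). miR-130a fell by 6.39 ± 0.58 (adjusted p = 2.07e-06), from 4982 ± 5208 to 32.9 ± 19.96 RPM. miR-31 fell by 6.50 ± 0.89, miR-20a* fell by 5.29 ± 0.72, miR-503 fell by 5.08 ± 0.69 and miR-322* fell by 4.68 ± 0.72. The hairpin entries mir-196b, mir-130a, mir-31 and mir-322 fell by 6.03 ± 0.80, 5.47 ± 0.73, 5.45 ± 0.98 and 4.55 ± 0.85 in the same order. In the other direction, miR-22 rose by 3.33 ± 0.60 (26851 ± 24769 against 2737 ± 1741 RPM, adjusted p = 0.000884) and miR-342-3p, hosted by the Evl gene, by 3.71 ± 0.59 (4110.4 ± 2590.1 against 491 ± 529 RPM). miR-138 rose by 5.62 ± 1.08, mir-150 by 4.69 ± 0.76 and miR-26b by 1.46 ± 0.49. miR-184 rose to 115 ± 74.5 RPM from a progenitor level of 0.335 ± 0.638 RPM (4 reads in 8 libraries), a log2 change of 5.83 ± 0.78. The call of miR-26b (adjusted p = 0.0385) was lost without HSC 1, CMP 1, CMP 2, CLP 1, CLP 2, CDP 2, cDC 1 or cDC 2 (adjusted p = 0.0566 to 0.0958). No filter on low entries ended the call of miR-26b (adjusted p = 0.0565), as did counting the CLP libraries as 1 (adjusted p = 0.0823).

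For splenic DC against progenitors, 146 of 611 entries passed (103 of them mature), 40 higher and 106 lower. This split depended on scaling, which moved the median of all entries by 1.04 (TMM), 0.76 (RLE) and 0.61 (quantile) on the log2 scale. TMM gave 175 (120 higher and 55 lower), RLE 163 (93 higher and 70 lower), quantile normalization 94 higher and 88 lower, edgeR 197 (147 higher and 50 lower) and DESeq2 200 (121 higher and 79 lower). The excess of lower calls belongs to the RPM scale.

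**Figure D3:**
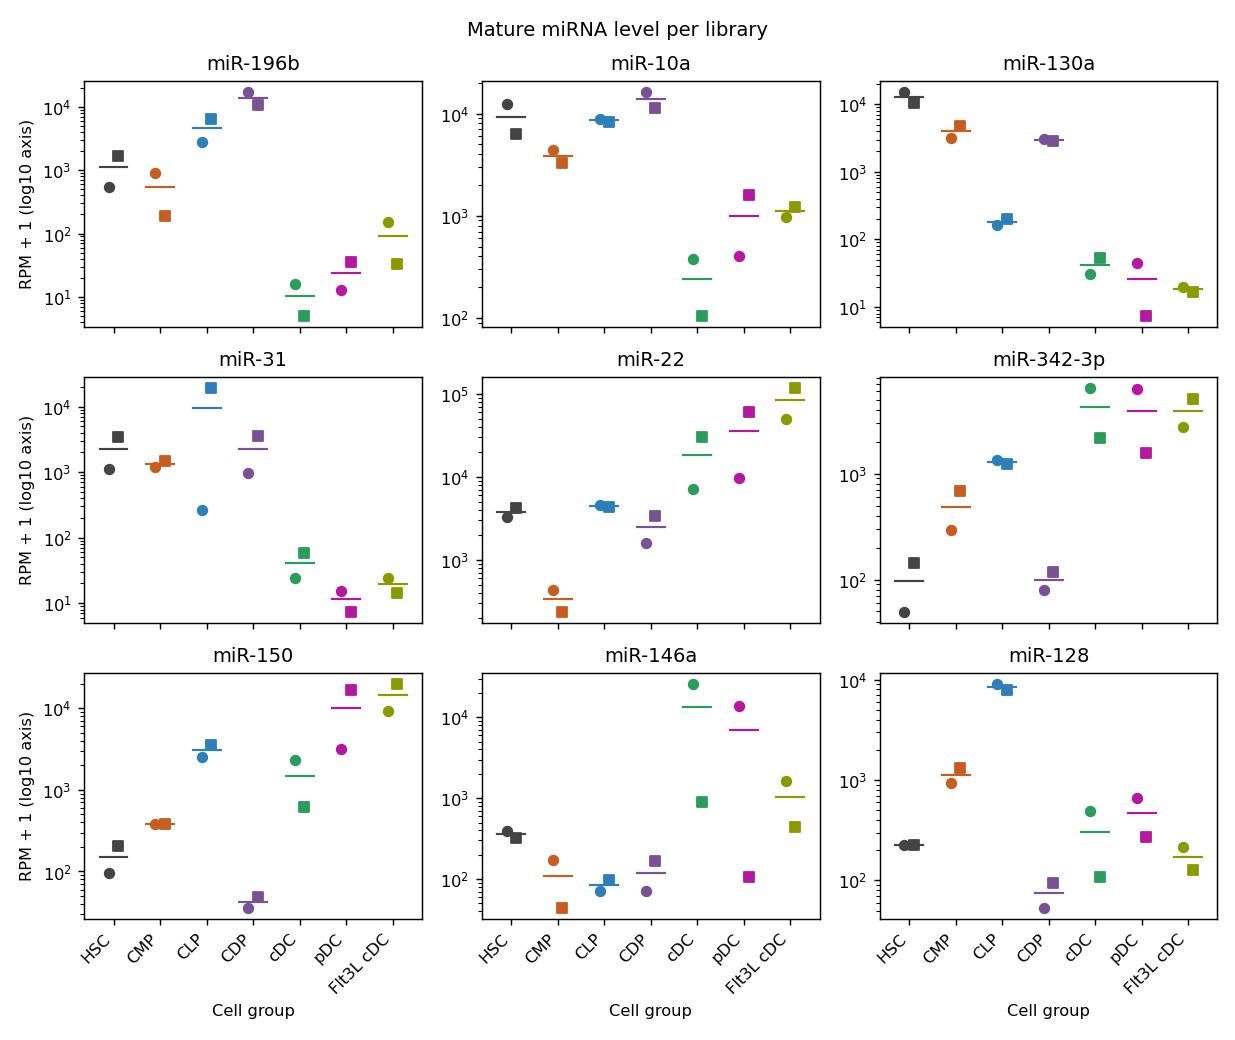
RPM + 1 on a log10 axis of 9 miRNAs in each library of the 7 cell groups (circles, replicate 1; squares, replicate 2; lines, group means). miR-196b averages 13894 RPM in CDP and 9.38 RPM in cDC, whereas miR-342-3p averages 98.4 RPM in CDP and 4296 RPM in cDC.

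Among the fixed lists, those of progenitor miRNAs were lower in splenic DC. Of 32 tested HSC-enriched entries, 12 fell and 20 did not pass (13 fell when adjusted over the list alone), among them miR-10a (-4.30 ± 0.55), miR-99a (-3.56 ± 0.54), miR-126-3p (-2.79 ± 0.72) and miR-125b-5p (-2.65 ± 0.62). The list was lower as a whole (camera, adjusted p = 0.000126, and adjusted p = 0.166 with an estimated correlation). Its summed level in pDC 2 (62079 RPM) nevertheless lay among the progenitor libraries (40576 to 101069 RPM), above the other DC libraries (14057 to 18568 RPM). Of 9 Hox-embedded entries 6 fell, including miR-10a and miR-196b (6 adjusted over the list alone; camera, adjusted p = 0.000252, and adjusted p = 0.217 with an estimated correlation). All 6 entries of the cluster of miR-221 and miR-222, known to restrain Kit, fell over all entries and adjusted over the list alone (0 higher and 4 lower with TMM; camera, adjusted p = 0.00142, and adjusted p = 0.212 with an estimated correlation). miR-222 went from 11181 ± 6967 to 1072 ± 808 RPM and miR-221 from 11790.0 ± 13735 to 885 ± 289.

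The proliferation-linked miR-17/92 and paralogue clusters had 18 of 38 entries lower and none higher (23 lower adjusted over the list alone; camera, adjusted p = 2.25e-05, and adjusted p = 0.407 with an estimated correlation), with miR-20a at -1.98 ± 0.63, miR-92a at -2.09 ± 0.58 and miR-19b at -2.29 ± 0.65. With TMM 4 of the 38 passed, all lower. Summed over the list, cDC 2 (113866 RPM) and pDC 1 (109209) lay above both CLP libraries (89009 and 82075), and pDC 2 (9464) far below every other library. Without miR-106b, pDC 1 (59506 RPM) lay below both CLP libraries (85123 and 78491), and cDC 2 (91966) still above them. In the miR-23/27/24 clusters 9 of 15 fell (13 adjusted over the list alone; 0 higher and 3 lower with TMM; camera, adjusted p = 0.000199, and adjusted p = 0.404 with an estimated correlation), led in abundance by miR-24 (4269 ± 2249 against 22012 ± 11926 RPM). The summed levels of cDC 1 (20217 RPM) and pDC 1 (22624) lay above that of CDP 1 (14813). In the miR-181 family 7 of 14 fell (9 adjusted over the list alone; 0 higher and 2 lower with TMM; camera, adjusted p = 0.0265, and adjusted p = 0.521 with an estimated correlation). miR-181b (-2.07 ± 0.57) and miR-181d (-3.24 ± 0.52) fell, whereas the abundant miR-181a did not pass (-0.02 ± 0.71). The family summed to 266820.0 RPM in pDC 2, above every progenitor library (44149 to 90193), to 66419.6 in cDC 2, and to 15651 and 19596 in cDC 1 and pDC 1. The rodent Sfmbt2 intronic cluster had 7 of 51 entries lower (4 adjusted over the list alone; 0 higher and 3 lower with TMM; camera, adjusted p = 0.0339, and adjusted p = 0.521 with an estimated correlation), such as miR-669p (-2.38 ± 0.81) and miR-297a (-3.23 ± 0.88). With entries of identical values counted once, 6 of 47 were lower.

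Several lists were higher in splenic DC. Of 31 myeloid and DC entries 8 rose, 2 fell and 21 did not pass (11 and 2 adjusted over the list alone; 15 higher and 0 lower with TMM; camera, adjusted p = 5.51e-05, and adjusted p = 0.384 with an estimated correlation). miR-146a, a brake on Toll-like receptor signalling, rose by 4.21 ± 1.08 (10132 ± 12122 against 166 ± 126 RPM) and miR-132 by 3.98 ± 0.96, whereas mir-21 (-2.83 ± 0.88) and miR-21* (-2.77 ± 0.89) fell, though not with TMM. The myeloid miR-223 (-0.11 ± 0.81) and miR-155 (-0.85 ± 0.53) did not pass. All 3 members of the cluster of miR-183, miR-96 and miR-182 rose (3 adjusted over the list alone; camera, adjusted p = 0.000532, and adjusted p = 0.235 with an estimated correlation), to 53.2 ± 37.9 RPM for miR-182, 27.4 ± 22.2 for miR-96 and 26.3 ± 21.9 for miR-183. pDC 2 held no read of them, while the other 3 DC libraries summed to 94.5 to 171 RPM. The miR-29 family was higher as a list with 1 of 8 entries called, mir-29b-2 (0 adjusted over the list alone; 6 higher and 0 lower with TMM; camera, adjusted p = 0.00216, and adjusted p = 0.288 with an estimated correlation). The let-7 family was higher as a list (8 higher and 0 lower with TMM; camera, adjusted p = 0.0265, and adjusted p = 0.521 with an estimated correlation) although its only call among 24 was let-7d*, which fell by 2.02 ± 0.60 (0 adjusted over the list alone). Of 29 lymphocyte entries 4 rose and 3 fell, the same adjusted over the list alone, without a list call (8 higher and 0 lower with TMM; camera, adjusted p = 0.367, and adjusted p = 0.521 with an estimated correlation). miR-150, a regulator of Myb, rose by 3.37 ± 0.59 and miR-20b fell, though not with TMM. The median of that list was -0.87 in RPM and 0.31 with TMM, while its mean was -0.16 and its test pointed up. That direction is relative to all entries, whose median was -0.69. With fry the unadjusted p was 0.353 for let-7, 0.0736 for the myeloid and DC list and 0.593 for lymphocyte miRNAs. It was 0.0216 for the miR-29 family and 0.00457 for the miR-183 cluster.

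In the miR-15/16 family 5 of 20 entries fell, all from the X-linked miR-322 and miR-503 genes, also adjusted over the list alone. miR-322 fell by 3.62 ± 0.69, whereas miR-16 was at 0.70 ± 0.50 and did not pass. The family was not called (5 higher and 5 lower with TMM; camera, adjusted p = 0.533, and adjusted p = 0.817 with an estimated correlation), and its median of -0.35 turned to 0.43 with TMM, 0.26 with RLE and 0.04 with quantile normalization. The miR-30 family had 0 of 16 called by limma over all entries or adjusted over the list alone, against 6 with TMM (camera, adjusted p = 0.0521, and adjusted p = 0.521 with an estimated correlation). The Dlk1-Dio3 imprinted cluster had 1 of 9 lower, miR-377, and 0 adjusted over the list alone (0 higher and 0 lower with TMM; camera, adjusted p = 0.367, and adjusted p = 0.521 with an estimated correlation).

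Markers of other cell types moved with splenic DC in part. Red cell markers had 2 of 10 entries higher (2 adjusted over the list alone; 5 higher and 0 lower with TMM; camera, adjusted p = 0.00184, and adjusted p = 0.166 with an estimated correlation). These were mir-451 at 24.6 ± 13.3 against 3.55 ± 4.01 RPM and miR-144 at 33.5 ± 39.7 against 2.41 ± 2.77 RPM. Epithelial markers had 5 of 13 higher (5 adjusted over the list alone; 8 higher and 0 lower with TMM; camera, adjusted p = 0.00109, and adjusted p = 0.384 with an estimated correlation), among them miR-200b at 616 ± 486 against 153 ± 178 RPM and miR-141 at 125 ± 99.5 against 12.3 ± 11.6 RPM. The epithelial sum of pDC 2 (291 RPM) lay below those of HSC 2 (2052) and CDP 2 (1977), while the other DC libraries held 1532 to 2498. Among 16 stromal and muscle entries miR-143 rose by 3.79 ± 0.74 and miR-152 fell, the same adjusted over the list alone (2 higher and 0 lower with TMM; camera, adjusted p = 0.261, and adjusted p = 0.552 with an estimated correlation). The median of that list was 0.04 and its mean -0.04. Of the 3 miR-126 entries, the endothelial and platelet list, miR-126-3p fell (2 lower adjusted over the list alone; 0 higher and 0 lower with TMM; camera, adjusted p = 0.178, and adjusted p = 0.521 with an estimated correlation). Liver and brain markers had 0 of 13 called by limma, also adjusted over the list alone, and 3 higher with TMM (camera, adjusted p = 0.116, and adjusted p = 0.521 with an estimated correlation).

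Of the other lists in this comparison, the Hox-embedded list and the miR-221 cluster had lower sums in all 4 DC libraries than in all 8 progenitor libraries. For let-7 all 4 DC sums (166472 to 286616 RPM) lay within the progenitor range (54859 to 345851), as did those of red cell miRNAs (235 to 371 within 0 to 424). The miR-29 sum of cDC 2 (4413), the myeloid and DC sums of cDC 2 and pDC 2 (70691 and 93029.9) and the Sfmbt2 sum of pDC 1 (2913) also lay within the progenitor ranges.

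**Figure D4:**
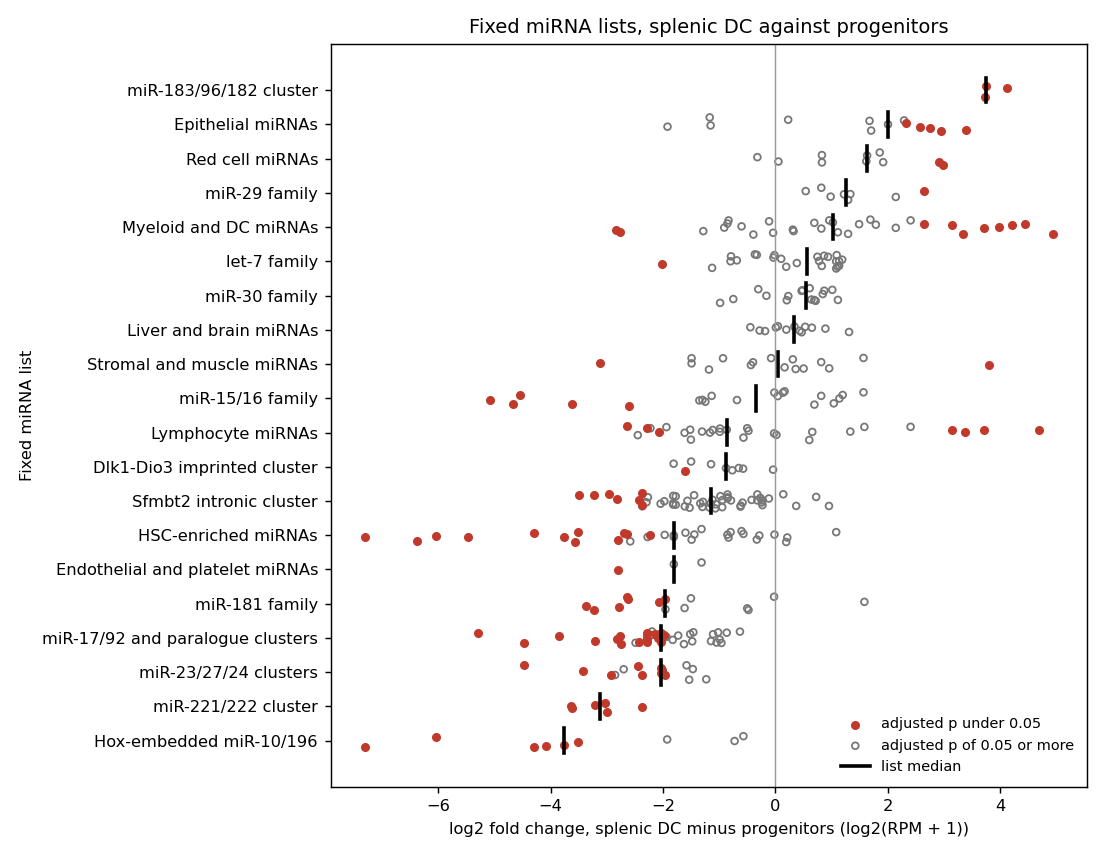
Log2 fold change of splenic DC against progenitors for each tested entry of the 20 fixed lists (filled red, adjusted p under 0.05; open grey, not; black bars, list medians). The median is -3.76 for the Hox-embedded list and -3.12 for the miR-221 cluster, both below 0 under every scaling tried, while that of the miR-15/16 family is -0.35 and above 0 with TMM, RLE and quantile normalization and that of the lymphocyte list is above 0 with TMM.

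CMP were compared with HSC for the first myeloid step. Members of the Dlk1-Dio3 imprinted cluster, linked to long-term stem cells, were lower in CMP as a list (camera, adjusted p = 0.000139, and adjusted p = 0.0437 with an estimated correlation). This was the only list call in any of the pairwise comparisons or in splenic DC against progenitors that held with an estimated correlation. The estimate for this cluster was -0.07, while those of the other lists lay between 0.0287 and 0.953. The check therefore made no allowance for positive correlation among the members of this cluster. The whole cluster summed to 259 ± 151 RPM in HSC and 28.5 ± 21.2 in CMP. Of its 9 entries 0 passed over all entries, and 2 were lower adjusted over the list alone, miR-379 (-4.49 ± 1.08) and miR-541 (-4.26 ± 1.44). The list median was -2.22, or -1.92 with 4 entries at their detection bound. HSC-enriched miRNAs were also lower (camera, adjusted p = 0.00373, and adjusted p = 0.297 with an estimated correlation), with miR-130a at 4002 ± 1183 against 12785 ± 3234 RPM and miR-10a at 3850.0 ± 768 against 9342 ± 4201 RPM. So were the Hox-embedded list (camera, adjusted p = 0.0264, and adjusted p = 0.590 with an estimated correlation) and the miR-15/16 family (camera, adjusted p = 0.00257, and adjusted p = 0.615 with an estimated correlation). The miR-15/16 sum of HSC 2 (114937 RPM) lay between those of CMP 1 (112880) and CMP 2 (134963), with HSC 1 at 392064. Lymphocyte miRNAs (camera, adjusted p = 0.00967, and adjusted p = 0.297 with an estimated correlation), the miR-30 family (camera, adjusted p = 0.0214, and adjusted p = 0.615 with an estimated correlation) and the Sfmbt2 cluster (camera, adjusted p = 0.0296, and adjusted p = 0.744 with an estimated correlation) were higher. The lymphocyte sums overlapped, with 57539 and 107927 RPM in CMP against 54492 and 97542 in HSC. Apart from the Dlk1-Dio3 cluster, 0 members of these lists passed over all entries or adjusted over the list alone. With fry the unadjusted p was 9.26e-05 for the Dlk1-Dio3 cluster and 0.0124 for HSC-enriched miRNAs. It was 0.0802 to 0.649 for the other lists named in this paragraph.

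Among myeloid miRNAs, miR-223, a regulator of granulocytes, stood at 23557 ± 21058 against 2942 ± 2174 RPM in CMP against HSC and miR-27a at 24981 ± 5418 against 5906 ± 2413 RPM. Neither passed (adjusted p = 0.666 and 0.675). For CMP against HSC, limma called 0 entries, with 44 at an unadjusted p under 0.05. edgeR called 0, DESeq2 11 and a limma fit on these 4 libraries alone 7. The smallest adjusted p was 0.417, for miR-379.

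CLP against HSC addressed the first lymphoid step, between groups that also differed in barcode. The lymphoid-linked miR-128 rose by 5.23 ± 0.93 (limma, adjusted p = 0.0102), from 222.4 ± 0.764 to 8406 ± 837 RPM, and its hairpin entry mir-128-1 by 5.76 ± 1.11. miR-150, a lymphocyte miRNA, rose by 4.43 ± 0.97 (3061 ± 739 against 149 ± 79.0 RPM). miR-122, best known from liver, rose by 6.68 ± 1.44 (330.3 ± 36.1 against 2.90 ± 3.10 RPM). The stem cell miRNA miR-130a fell by 6.11 ± 0.95 (181.8 ± 23.7 against 12785 ± 3234 RPM). These 5 entries were all that passed, 4 higher and 1 lower, with both CLP libraries outside the range of both HSC libraries. miR-130a, miR-128 and mir-128-1 no longer passed without HSC 1, HSC 2, CLP 1 or CLP 2 (adjusted p = 0.0758 to 0.279), and miR-122 and miR-150 without HSC 1, HSC 2, CMP 1, CMP 2, CLP 1, CLP 2, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0710 to 0.460). Counting the CLP libraries as 1 ended all of these calls (adjusted p = 0.121 to 0.410), a pseudocount of 0.1 the calls of miR-122 and miR-150 (adjusted p = 0.0538 to 0.207), and TMM the call of miR-150 (adjusted p = 0.0686).

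Of 29 lymphocyte entries 3 rose (5 adjusted over the list alone and 5 with RLE or quantile normalization; camera, adjusted p = 0.00280, and adjusted p = 0.543 with an estimated correlation). The let-7 family was higher as a list with 0 of 24 members called, also adjusted over the list alone (camera, adjusted p = 0.000448, and adjusted p = 0.619 with an estimated correlation), with let-7a at 83813 ± 5998 against 23411 ± 21268 RPM and let-7c at 62822 ± 5461 against 16584 ± 11796 RPM. The Sfmbt2 cluster was higher (camera, adjusted p = 0.00116, and adjusted p = 0.734 with an estimated correlation). The miR-17/92 clusters (camera, adjusted p = 0.0102, and adjusted p = 0.734 with an estimated correlation), the miR-15/16 family (camera, adjusted p = 0.0423, and adjusted p = 0.734 with an estimated correlation) and stromal markers (camera, adjusted p = 0.0299, and adjusted p = 0.734 with an estimated correlation) were lower, with 4 stromal members lower adjusted over the list alone and 0 over all entries. The miR-15/16 sum of HSC 2 (114937 RPM) nevertheless lay below both CLP libraries (128108 and 139743), with HSC 1 at 392064.

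For CLP against HSC, the 5 calls became 0 without HSC 1, HSC 2, CLP 1 or CLP 2 and 0 with the CLP libraries counted as 1. They became 3 without CMP 1, CMP 2, Flt3L cDC 1 or Flt3L cDC 2, 8 without CDP 1 or CDP 2, 10 without cDC 2 and 23 without pDC 1 or pDC 2. RLE moved the median of all entries by 0.31 and quantile normalization by 0.23, and the latter called 15 (10 higher and 5 lower). DESeq2 called 24 (15 higher and 9 lower), and a fit on these 4 libraries alone 78 (24 higher and 54 lower).

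CLP against CMP set the lymphoid beside the myeloid branch. The lowest adjusted p was 0.0937, for miR-130a (181.8 ± 23.7 against 4002 ± 1183 RPM), miR-331-3p (114 ± 5.13 against 2.71 ± 3.83 RPM) and miR-147 (47.2 ± 5.04 against 1.35 ± 1.91 RPM), named after their values were seen. miR-221 stood at 33598 ± 4892 against 2755 ± 1717 RPM, miR-22 at 4408 ± 153 against 332 ± 135 RPM and miR-106b at 3735 ± 213 against 91045 ± 44152 RPM, none of them past the threshold. As lists, the Hox-embedded miRNAs (camera, adjusted p = 0.00463, and adjusted p = 0.767 with an estimated correlation) and the let-7 family (camera, adjusted p = 0.0154, and adjusted p = 0.767 with an estimated correlation) were higher in CLP and the miR-17/92 clusters lower (camera, adjusted p = 0.000217, and adjusted p = 0.767 with an estimated correlation). These lists had 0 members called over all entries or adjusted over the list alone. For CLP against CMP limma called 0 entries, with 51 at an unadjusted p under 0.05, edgeR 0 and DESeq2 21. Without pDC 1 or without pDC 2, which entered through the pooled spread, limma called 11, and in a fit on the 4 libraries compared 23.

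CDP against CMP asked what changed with commitment to the DC lineage. miR-196b rose by 5.03 ± 1.11 (limma, adjusted p = 0.0480), from 542 ± 497 RPM in CMP to 13894 ± 4542 in CDP, its highest level of the 7 groups. miR-128 fell by 3.96 ± 0.93 (73.4 ± 29.3 against 1125 ± 275 RPM). miR-140 fell from 558 ± 195.9 to 8.79 ± 12.4 RPM (2 reads in CDP) and miR-149 from 117 ± 11.4 to 4.39 ± 6.21 RPM (1 read). mir-5100 had 293 ± 93.4 RPM in CMP and no read in CDP, at least 15.3-fold lower. miR-377 had 4 reads in CDP (24.9 ± 2.00 RPM) and none in CMP. miR-139-3p and miR-669f-3p, without a read in CDP, were at least 1.803-fold and 2.18-fold lower. mir-5100 no longer passed without CMP 1 or CMP 2 (adjusted p = 0.177 to 0.185), and miR-196b without HSC 1, HSC 2, CMP 1, CMP 2, CLP 1, CLP 2, CDP 2, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0649 to 0.250). The call of miR-128 ended without HSC 1, HSC 2, CMP 1, CMP 2, CLP 1, CLP 2, CDP 1, CDP 2, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0659 to 0.250), and those of miR-140 and miR-149 without HSC 1, HSC 2, CMP 1, CMP 2, CLP 1, CLP 2, CDP 2, cDC 2, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0518 to 0.250). No filter ended the calls of miR-196b, miR-140, miR-149 and miR-128 (adjusted p = 0.0559 to 0.0950), a fit on mature entries alone all of these calls (adjusted p = 0.0520) and CLP counted as 1 library the calls of miR-196b, miR-140, miR-149 and miR-128 (adjusted p = 0.0812 to 0.0836). A fit on CDP and CMP alone ended the calls of miR-196b, miR-140 and miR-149 (adjusted p = 0.0739 to 0.150), edgeR the calls of miR-196b and miR-149 (adjusted p = 0.0648 to 0.108), DESeq2 the call of miR-149 (adjusted p = 0.0997) and a pseudocount of 10 the call of miR-140 (adjusted p = 0.0716).

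The Hox-embedded list was higher in CDP with 1 of 9 called, miR-196b (2 adjusted over the list alone and 2 with quantile normalization; camera, adjusted p = 0.00198, and adjusted p = 0.479 with an estimated correlation), and miR-10a at 13739 ± 3457 against 3850.0 ± 768 RPM. The Dlk1-Dio3 cluster was higher with 1 of 9 called, miR-377 (1 adjusted over the list alone; camera, adjusted p = 0.0373, and adjusted p = 0.468 with an estimated correlation). The miR-15/16 family was higher with 0 of 20 called (1 higher and 1 lower adjusted over the list alone; 1 higher and 1 lower with TMM; camera, adjusted p = 0.0373, and adjusted p = 0.773 with an estimated correlation), with miR-15b at 89426 ± 1883 against 23438 ± 2286 RPM. miR-223 stood at 1675 ± 1470.4 against 23557 ± 21058 RPM and miR-27a at 1467 ± 720.5 against 24981 ± 5418 RPM, neither past the threshold.

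For CDP against CMP 10 entries passed, 3 higher and 7 lower. TMM, which moved the median of all entries by -0.53, gave 51 (5 higher and 46 lower), quantile normalization (0.43) 24 (13 higher and 11 lower), edgeR 9 (0 higher and 9 lower) and DESeq2 40 (20 higher and 20 lower). The count was 0 without CMP 1 or CMP 2, 1 without HSC 1, HSC 2, CLP 1, CLP 2 or CDP 2, 3 without Flt3L cDC 1 or 2, 5 without cDC 2, 47 without CDP 1 and 49 without pDC 1 or pDC 2. A fit on these 4 libraries alone called 45 (4 higher and 41 lower).

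cDC against CDP followed maturation to the conventional subset. The largest drop was that of miR-196b, which fell by 10.57 ± 1.11 (limma, adjusted p = 2.37e-05), from 13894 ± 4542 RPM in CDP to 9.38 ± 7.54 in cDC. miR-10a fell by 6.08 ± 0.89 (242 ± 194 against 13739 ± 3457 RPM), miR-130a fell by 6.20 ± 0.95, miR-92a-1* fell by 6.83 ± 1.19, miR-31 fell by 5.60 ± 1.45 and miR-20a* fell by 5.53 ± 1.18. miR-342-3p rose by 5.26 ± 0.96 (4296 ± 2985 against 98.4 ± 27.3 RPM) and miR-150 by 4.85 ± 0.97 (1477 ± 1218 against 41.1 ± 8.43 RPM). The inflammatory regulator miR-132 reached 145 ± 144 RPM with no read in CDP, at least 7.56-fold higher. By the same bound mir-146a (696 ± 884 RPM) was at least 36.3-fold, mir-150 15.6-fold, miR-592 12.8-fold, miR-184 7.35-fold, miR-5107 6.50-fold and mir-138-1 5.44-fold higher. miR-138 stood at 376 ± 208 against 4.39 ± 6.21 RPM and mir-342 at 268 ± 187 against 4.39 ± 6.21 RPM, with 1 read each in CDP. Calls of miR-138, miR-31 and mir-342 ended without CDP 2 or cDC 1 (adjusted p = 0.0524 to 0.108), and those of miR-132, mir-146a and miR-20a* without cDC 1 (adjusted p = 0.0628 to 0.0900). A fit on cDC and CDP alone ended all of these calls (adjusted p = 0.117 to 0.239), no filter the calls of miR-138 and miR-31 (adjusted p = 0.0551 to 0.0612) and DESeq2 the call of mir-138-1 (adjusted p = 0.251).

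Of 31 myeloid and DC entries 6 rose and none fell (12 adjusted over the list alone; 14 higher and 0 lower with TMM; camera, adjusted p = 0.000348, and adjusted p = 0.482 with an estimated correlation). The abundant miR-142-3p (27682 ± 10549 against 3346 ± 2223 RPM), miR-22 (18494 ± 16069 against 2498 ± 1259 RPM) and miR-146a (13269 ± 17506 against 118 ± 66.8 RPM) did not pass over all entries. All 3 members of the miR-183 cluster rose (3 adjusted over the list alone; camera, adjusted p = 0.00487, and adjusted p = 0.415 with an estimated correlation), each from no read in CDP, miR-182 to 63.4 ± 14.3 RPM. Without a read, CDP could hold up to 19.2 RPM of each, and the whole cluster summed to 133 ± 53.8 RPM in cDC. The depth of CDP therefore bounds these rises only weakly. The miR-30 family was higher with mir-30c-1 and mir-30c-2 of 16 called (2 adjusted over the list alone; 4 higher and 0 lower with TMM; camera, adjusted p = 0.0358, and adjusted p = 0.482 with an estimated correlation). HSC-enriched miRNAs were lower with 7 of 32 called (8 adjusted over the list alone; camera, adjusted p = 0.000348, and adjusted p = 0.136 with an estimated correlation). So were Hox-embedded ones with 5 of 9 (6 adjusted over the list alone; camera, adjusted p = 2.70e-05, and adjusted p = 0.136 with an estimated correlation). The miR-221 cluster (camera, adjusted p = 0.00606, and adjusted p = 0.266 with an estimated correlation) had 0 of 6 called and 4 lower adjusted over the list alone. The miR-181 family (0 higher and 0 lower with TMM; camera, adjusted p = 0.00606, and adjusted p = 0.482 with an estimated correlation) had 1 of 14 lower, miR-181d, also adjusted over the list alone. In the Sfmbt2 cluster 6 of 51 fell (5 of 47 with entries of identical values counted once; 7 adjusted over the list alone; camera, adjusted p = 0.00410, and adjusted p = 0.482 with an estimated correlation), including miR-669p (39.5 ± 48.2 against 1245 ± 1295 RPM) and miR-297a and mir-466d at 4.41 ± 6.24 against 195 ± 209 RPM and 2.15 ± 1.13 against 138 ± 28.6 RPM. The calls of miR-297a and miR-669p ended without CDP 1 or cDC 2 (adjusted p = 0.107 to 0.156). In the miR-17/92 clusters 5 of 38 fell (5 adjusted over the list alone; camera, adjusted p = 0.000761, and adjusted p = 0.482 with an estimated correlation). The list median of -1.06 turned to 0.05 with TMM. Red cell markers had 3 of 10 higher, mir-486, mir-3107 and mir-451 (4 adjusted over the list alone and 1 with quantile normalization; camera, adjusted p = 0.00308, and adjusted p = 0.136 with an estimated correlation), with mir-486 at 29.0 ± 7.71 RPM. The values of mir-486 and mir-3107 were the same in all 4 libraries compared. In CDP 2 a single read was worth 23.5 RPM, near the level of mir-486 in cDC. Both red cell sums of cDC (241 and 371 RPM) lay between those of CDP 1 (0) and CDP 2 (424).

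For cDC against CDP 70 entries passed, 36 higher and 34 lower. TMM, which moved the median by 1.08, gave 132 (102 higher and 30 lower), RLE (0.44) 111 (72 higher and 39 lower) and edgeR 71 (51 higher and 20 lower). The count was 39 without cDC 1, 133 without pDC 1 and 134 without pDC 2, and 0 when the spread came from these 4 libraries alone.

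pDC against CDP followed maturation to the plasmacytoid subset. miR-150 rose by 7.46 ± 0.97 (limma, adjusted p = 0.000144), from 41.1 ± 8.43 RPM in CDP to 9997 ± 9598 in pDC. miR-342-3p rose by 5.01 ± 0.96 and miR-22 by 3.38 ± 0.98 (35208 ± 36096 against 2498 ± 1259 RPM). miR-196b fell by 9.30 ± 1.11 (23.1 ± 15.8 against 13894 ± 4542 RPM), miR-503 fell by 7.53 ± 1.13, miR-31 fell by 7.42 ± 1.45, miR-130a fell by 7.34 ± 0.95 and miR-20a* fell by 6.52 ± 1.18. miR-152 fell by 6.03 ± 1.43 and mir-92a-1 fell by 5.87 ± 0.98. mir-150 (402 ± 419 RPM), miR-592 (316 ± 372) and mir-146a (161 ± 219.9), without a read in CDP, were at least 20.9-fold, 16.5-fold and 8.41-fold higher. Rises were called from 1 to 3 CDP reads for miR-138 (514 ± 699 against 4.39 ± 6.21 RPM), miR-181a-1* (295 ± 370.5 against 4.39 ± 6.21 RPM), mir-342 (217 ± 258 against 4.39 ± 6.21 RPM), miR-340-3p (181.7 ± 201 against 4.39 ± 6.21 RPM) and miR-339-5p (203 ± 215 against 13.2 ± 18.6 RPM). The hairpin mir-31 fell by 6.83 ± 1.60, a call that ended without CDP 2 (adjusted p = 0.0701). That of miR-152 ended without pDC 2 (adjusted p = 0.0659), of mir-342 without CDP 2 or pDC 1 (adjusted p = 0.0897 to 0.133) and of miR-181a-1* without HSC 1, HSC 2, CDP 2, pDC 2 or Flt3L cDC 1 (adjusted p = 0.0501 to 0.164). miR-138 no longer passed without HSC 1, HSC 2, CMP 1, CMP 2, CLP 1, CLP 2, CDP 2, cDC 1, cDC 2, pDC 1, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0533 to 0.335), mir-146a without HSC 1, HSC 2, CMP 1, CMP 2, CLP 1, CLP 2, CDP 1, CDP 2, pDC 1, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0612 to 0.314), and miR-340-3p and miR-339-5p without HSC 1, HSC 2, CMP 1, CMP 2, CLP 1, CLP 2, CDP 2, pDC 1, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0550 to 0.321). A fit on pDC and CDP alone ended all of these calls (adjusted p = 0.248 to 0.396). No filter ended the calls of mir-146a, miR-138, miR-181a-1*, miR-340-3p and miR-339-5p (adjusted p = 0.0643 to 0.114), a pseudocount of 10 the calls of mir-146a, miR-138, miR-340-3p, miR-339-5p and mir-31 (adjusted p = 0.0557 to 0.162) and one of 0.1 the calls of miR-138 and miR-339-5p (adjusted p = 0.0514 to 0.0736). CLP counted as 1 library ended the calls of mir-146a, miR-138, miR-340-3p and miR-339-5p (adjusted p = 0.0642 to 0.0734), and mature entries alone the calls of miR-138 and miR-339-5p (adjusted p = 0.0571).

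In the miR-17/92 clusters 9 of 38 entries fell (13 adjusted over the list alone; 0 higher and 5 lower with TMM; camera, adjusted p = 1.20e-06, and adjusted p = 0.528 with an estimated correlation), among them miR-18a (-4.59 ± 1.37) and mir-106b (-5.00 ± 1.60). The clusters summed to 109209 RPM in pDC 1 and 9464 in pDC 2, against 149507 and 178550.0 in CDP. Of 31 myeloid and DC entries 8 rose and mir-21 fell (8 and 2 adjusted over the list alone; 16 higher and 1 lower with TMM; camera, adjusted p = 0.00365, and adjusted p = 0.528 with an estimated correlation). The miR-29 family had 2 of 8 higher, mir-29b-1 and mir-29b-2 (2 adjusted over the list alone; 6 higher and 0 lower with TMM; camera, adjusted p = 0.00766, and adjusted p = 0.421 with an estimated correlation). The miR-30 family was higher with 0 of 16 called, also adjusted over the list alone (7 higher and 0 lower with TMM; camera, adjusted p = 0.0304, and adjusted p = 0.528 with an estimated correlation). Hox-embedded entries fell in 5 of 9 cases (6 adjusted over the list alone; 0 higher and 3 lower with TMM; camera, adjusted p = 0.000877, and adjusted p = 0.282 with an estimated correlation), with miR-10a at 1002 ± 844 against 13739 ± 3457 RPM. The miR-221 cluster had mir-221 lower of 6 (4 adjusted over the list alone; camera, adjusted p = 0.00924, and adjusted p = 0.282 with an estimated correlation). HSC-enriched miRNAs had 7 of 32 lower (8 adjusted over the list alone; 1 higher and 4 lower with TMM; camera, adjusted p = 0.00493, and adjusted p = 0.282 with an estimated correlation). The list median of -0.95 turned to 0.54 with TMM, and the sum of pDC 2 (62079 RPM) lay between those of CDP 1 and CDP 2 (93278 and 47508). In the miR-15/16 family 6 of 20 fell (6 lower and 2 higher adjusted over the list alone; 2 higher and 3 lower with TMM; camera, adjusted p = 0.0304, and adjusted p = 0.572 with an estimated correlation), such as miR-15b (-3.56 ± 0.90). Its median of -1.91 turned to 0.02 with TMM. Red cell markers had 3 of 10 higher, mir-451, miR-144 and miR-451 (4 adjusted over the list alone; camera, adjusted p = 0.00257, and adjusted p = 0.253 with an estimated correlation), with miR-451 at 41.4 ± 2.03 RPM. Both red cell sums of pDC (298 and 235 RPM) lay between those of CDP 1 (0) and CDP 2 (424).

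For pDC against CDP 81 entries passed, 34 higher and 47 lower. TMM, which moved the median by 1.59, gave 165 (135 higher and 30 lower), RLE (0.83) 126 (86 higher and 40 lower), quantile normalization (0.36) 110 (61 higher and 49 lower), edgeR 100 (81 higher and 19 lower) and DESeq2 105 (62 higher and 43 lower). The count was 45 without HSC 1 or HSC 2, 47 without CMP 1, 46 without CMP 2, 50 without CLP 1, 51 without CLP 2, 38 without CDP 2 and 52 without Flt3L cDC 1. It was 0 when the spread came from these 4 libraries alone.

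pDC against cDC set the splenic subsets side by side. Across miRNAs, pDC 1 correlated more closely with cDC 1 (Pearson r 0.942) than with pDC 2 (0.692). No single miRNA separated them past the threshold. miR-150 stood at 9997 ± 9598 against 1477 ± 1218 RPM, miR-126-3p at 1969 ± 2545 against 121 ± 65.6 RPM and miR-10a at 1002 ± 844 against 242 ± 194 RPM, each with both pDC libraries above both cDC libraries. The spread within pDC was wide. All miR-126 entries summed to 195 RPM in pDC 1 and 4165 in pDC 2, against 253 and 166 in cDC. The Hox-embedded list, which holds miR-10a, summed to 428 and 1661 in pDC, against 432 and 112 in cDC. In both sums pDC 1 lay between the cDC libraries. miR-181a stood at 130722 ± 162649 against 34619 ± 30049 RPM, where pDC 1 held 15711 and pDC 2 245732 RPM. miR-22 (35208 ± 36096 against 18494 ± 16069 RPM), miR-223 (7676 ± 9723 against 7212 ± 8114 RPM) and miR-155 (2126 ± 1359 against 1659.7 ± 499.9 RPM) overlapped. As lists, the miR-29 family (camera, adjusted p = 0.0131, and adjusted p = 0.758 with an estimated correlation), the miR-181 family (camera, adjusted p = 0.0307, and adjusted p = 0.758 with an estimated correlation) and the Sfmbt2 cluster (camera, adjusted p = 0.0289, and adjusted p = 0.758 with an estimated correlation) were higher in pDC. The miR-17/92 clusters (camera, adjusted p = 0.0185, and adjusted p = 0.758 with an estimated correlation), the miR-15/16 family (camera, adjusted p = 0.0185, and adjusted p = 0.758 with an estimated correlation), the miR-183 cluster (camera, adjusted p = 0.0307, and adjusted p = 0.758 with an estimated correlation) and epithelial markers (camera, adjusted p = 0.0318, and adjusted p = 0.758 with an estimated correlation) were lower. No member of these lists passed, over all entries or adjusted over the list alone. Tested on their own with fry, these lists had unadjusted p-values of 0.128 to 0.688. For the lower lists only pDC 2 lay below both cDC libraries in summed level. The sums of pDC 1 lay between those of cDC 1 and cDC 2 for the miR-17/92 clusters, the miR-15/16 family, the miR-183 cluster (163 RPM, and 0 in pDC 2) and epithelial markers (2255, and 291 in pDC 2). For the miR-181 family pDC 1 (19596) also lay between the cDC libraries, and pDC 2 stood at 266820.0. For the Sfmbt2 cluster pDC 2 (1624) lay between cDC 2 (1093) and cDC 1 (2212), and pDC 1 (2913) above both. The miR-29 sums of pDC (23723 and 26405) lay above both of cDC, where cDC 1 stood at 20217 and cDC 2 at 4413. The number of lists called, 7 here, was 1 without cDC 2, 2 without pDC 2 and 9 without pDC 1.

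For pDC against cDC limma called 0 entries, with 38 at an unadjusted p under 0.05, edgeR 0 and DESeq2 21. Both libraries of one subset lay outside those of the other for 22.9% of entries, where chance gives 33.3%. Without pDC 1 limma called 66 entries, and with Flt3L cDC, which share the barcode of pDC, in place of cDC it called 34.

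Flt3L cDC against cDC asked how cultured cells of the conventional phenotype differ from those of the spleen. miR-23a rose by 3.42 ± 0.97 (limma, adjusted p = 0.0300; 7143 ± 1633 against 912 ± 895 RPM), miR-23b by 3.29 ± 0.90 and miR-150 by 3.49 ± 0.97 (14453 ± 7447 against 1477 ± 1218 RPM). Without a read in splenic cDC, miR-667* (594 ± 527 RPM) was at least 360.3-fold, miR-466o-3p (541 ± 412) 328-fold, miR-205 (217 ± 146) 131-fold and miR-186* (507 ± 668) 308-fold higher. miR-92a-1* rose by 6.06 ± 1.19, miR-92b by 5.06 ± 1.53, mir-5100 by 5.21 ± 1.38 and mir-10a by 4.77 ± 1.34, while miR-3107* (183 ± 38.5 against 0.675 ± 0.955 RPM) and miR-1953 (131 ± 99.1 against 1.81 ± 1.60 RPM) rose from 2 reads in cDC. miR-132 (145 ± 144 RPM in cDC), miR-592 (246 ± 193), miR-1941-5p (152 ± 36.1) and miR-184 (141 ± 20.95) had no read in Flt3L cDC and were at least 78.7-fold, 134-fold, 82.5-fold and 76.5-fold lower. miR-106a fell by 6.75 ± 1.68 (21.5 ± 9.49 against 2955 ± 2606 RPM), mir-138-1 fell by 5.13 ± 1.34, mir-30c-1 fell by 4.64 ± 1.44 and mir-26b fell by 3.22 ± 0.88. mir-146a (3.06 ± 2.33 against 696 ± 884 RPM) and miR-5107 (0.353 ± 0.500 against 125 ± 30.8 RPM) fell to 3 reads and 1 read. The call of miR-92a-1* ended without Flt3L cDC 2 (adjusted p = 0.0748), of miR-1941-5p without Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0572 to 0.0645) and of mir-138-1 without cDC 1 or Flt3L cDC 1 (adjusted p = 0.129 to 0.202). Those of miR-106a, miR-132, mir-146a and mir-5100 ended without cDC 1, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0853 to 0.222). mir-10a no longer passed without CLP 1, CLP 2, cDC 2, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0515 to 0.256), nor did mir-26b without CLP 1, CLP 2, cDC 1, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0515 to 0.190). The same held for mir-30c-1 without HSC 1, HSC 2, CMP 1, CMP 2, CLP 1, CLP 2, cDC 1, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0740 to 0.285) and miR-92b without HSC 1, HSC 2, CMP 1, CMP 2, CLP 1, CLP 2, cDC 1, cDC 2, Flt3L cDC 1 or Flt3L cDC 2 (adjusted p = 0.0593 to 0.217). A fit on Flt3L cDC and cDC alone ended all of these calls (adjusted p = 0.0930 to 0.203). No filter ended the calls of miR-92b, miR-106a, mir-146a, mir-138-1 and mir-30c-1 (adjusted p = 0.0522 to 0.0737), and a pseudocount of 0.1 the calls of miR-92b, mir-146a, mir-138-1 and mir-30c-1 (adjusted p = 0.0629 to 0.138). CLP counted as 1 library ended the calls of miR-92b, mir-10a, mir-30c-1 and mir-26b (adjusted p = 0.0515 to 0.0757), edgeR the calls of mir-5100 and mir-10a (adjusted p = 0.0647 to 0.0873) and DESeq2 the calls of miR-667* and mir-138-1 (adjusted p = 0.154 to 0.254).

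All 3 members of the miR-183 cluster fell, without a read in Flt3L cDC (3 adjusted over the list alone; camera, adjusted p = 0.00445, and adjusted p = 0.373 with an estimated correlation). Of 31 myeloid and DC entries 4 fell (4 adjusted over the list alone; camera, adjusted p = 0.250, and adjusted p = 0.885 with an estimated correlation), among them miR-132 and mir-146a. miR-223 (16121 ± 8269 against 7212 ± 8114 RPM), miR-155 (8032 ± 71.2 against 1659.7 ± 499.9 RPM) and miR-342-3p (3909 ± 1625 against 4296 ± 2985 RPM) did not pass. The Hox-embedded list was higher with mir-10a and mir-196a-1 of 9 called (4 adjusted over the list alone; camera, adjusted p = 0.0188, and adjusted p = 0.458 with an estimated correlation). The Dlk1-Dio3 cluster was higher with miR-410, mir-127 and miR-667* of 9 called (5 adjusted over the list alone; camera, adjusted p = 0.0188, and adjusted p = 0.373 with an estimated correlation). Lymphocyte miRNAs were lower as a list (0 higher and 5 lower with TMM; camera, adjusted p = 0.0313, and adjusted p = 0.373 with an estimated correlation), with miR-342-5p lower, miR-150 higher and 0 of 29 called adjusted over the list alone. Their summed level was not lower, with 68707 and 164731 RPM in Flt3L cDC against 73079 and 115070 in cDC. Stromal and muscle markers were lower, with miR-143 and miR-195 of 16 called (5 adjusted over the list alone; 0 higher and 5 lower with TMM; camera, adjusted p = 0.000541, and adjusted p = 0.373 with an estimated correlation). The stromal sum of Flt3L cDC 1 (664 RPM) lay between those of cDC 1 (1836) and cDC 2 (604), and that of Flt3L cDC 2 (331) below both. miR-143 had 75.8 ± 63.3 RPM in cDC and no read in Flt3L cDC, at least 41.1-fold lower. Red cell entries summed to 710.0 ± 238 RPM in Flt3L cDC and 306 ± 91.6 RPM in cDC.

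For Flt3L cDC against cDC 67 entries passed, 48 higher and 19 lower. TMM, which moved the median by -0.65, gave 89 (41 higher and 48 lower), quantile normalization (-0.26) 98 (58 higher and 40 lower), edgeR 61 (20 higher and 41 lower) and DESeq2 110 (50 higher and 60 lower). The count was 41 without cDC 1, 32 without Flt3L cDC 1, 26 without Flt3L cDC 2 and 101 without pDC 1. It was 0 when the spread came from these 4 libraries alone.

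Across the 7 groups as a whole, the F test asked which miRNAs varied at all. miR-130a varied most firmly (limma F test, adjusted p = 8.53e-06), from 12785 ± 3234 RPM in HSC to 17.2 ± 2.33 in Flt3L cDC. miR-196b and miR-667* followed (adjusted p = 3.91e-05 for each), then miR-466o-3p (7.19e-05) and miR-150 (0.000122). miR-22 went from 332 ± 135 RPM in CMP to 83307 ± 47067 in Flt3L cDC, and miR-10a from 242 ± 194 in cDC to 13739 ± 3457 in CDP. For miRNAs differing among the 7 groups 184 of 611 entries passed, 122 of them mature. The count was 91 without HSC 1, 94 without HSC 2, 92 without CMP 1, 94 without CMP 2, 82 without CLP 1, 72 without CLP 2, 97 without Flt3L cDC 1, 95 without Flt3L cDC 2 and 290 without pDC 1. DESeq2 called 289.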

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

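All tests in this part were chosen after the results they bear on were seen, except the rule for values far from the others, which was set beforehand. That rule looked for 1 library far from the rest of its set in 40 tests and found 3, where chance gives about 5%. Among the 4 splenic DC libraries, pDC 2 stood far below the others for miR-184 (6.13 RPM) and for miR-503 (0.995 RPM), and pDC 1 stood far above them in the number of entries detected (1039).

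pDC 1 resembled cDC 1 (Pearson r 0.942 over 224 entries, across miRNAs rather than independent replicates) more than its own replicate (0.692), while the cDC pair stood at 0.829. The values of the 10 most abundant entries of pDC 2 did not by themselves account for this. Without them the pDC pair correlated at 0.635 and pDC 1 with cDC 1 at 0.932, over 214 entries. Whether a few miRNAs taking most reads of pDC 2 acted on the other entries cannot be decided by this test. A common lowering of those entries would leave r nearly unchanged. A swap between a pDC and a cDC library cannot be told apart from a likeness of these libraries, since cDC 2 correlated better with cDC 1 than with pDC 2 by 0.0926 (95% interval 0.0366 to 0.151 over 1000 resamplings of entries), whereas exchanging pDC 1 and cDC 2 would raise r within both groups (0.942 in place of 0.829, and 0.736 in place of 0.692), and pDC 2 lay closest to Flt3L cDC 2 (0.864). A single wrong label of pDC 1 stays open too and would change what every pDC value means, because its ratio of miR-106b to miR-93 (3.79) lay nearer to that of cDC 1 (2.56) than of pDC 2 (0.0424). Reads of pDC 1 carried over into cDC 1 also stay open, since the ratio of cDC 1 to pDC 1 over 75 abundant entries had a 5th percentile of 0.459 and a lowest value of 0.0831, which bounds a carried share without excluding one, and a real likeness of the splenic subsets was not tested.

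miR-106b was low relative to miR-93 in the libraries of the barcode shared by CLP, pDC and Flt3L cDC, with a median ratio 12.5-fold below that of the other 8 libraries. A ligation that depends on the 5′ barcode stays open. Of the 35 ways to place that barcode on 3 of the 7 groups, the real one gave the lowest mean ratio (exact permutation p = 0.0286, the smallest this design can give), yet pDC 1, with the same labelled barcode, stood at 3.79 among the other barcodes, which leaves its barcode label in doubt. Differences among the cell groups in the stability or processing of miR-106b were not tested and stay open, since barcode and group go together.

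miR-31 stood at 19092 RPM in CLP 2 and at 264 RPM in CLP 1, 72.4-fold apart. Reads or cells from another library of the series were argued against, because the highest level in any other library was 3506 RPM. Uneven amplification of 1 molecule cannot be told apart from a difference between the cells, since 6 of 85 abundant entries differed more than 2-fold, among them mir-21 (10.02-fold), mir-15a (3.52-fold), mir-16-2 (2.48-fold) and miR-196b (2.35-fold). The hairpin mir-31 differed 48.5-fold. No biological explanation was tested, since the labels give no difference between these libraries.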

How the results depend on the processing

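TMM, RLE, edgeR and DESeq2 on recovered reads, mature entries alone, CLP counted as 1 library and the filter at 1 read were chosen after seeing the data. The other alternatives and the splits were planned. The 86 named calls kept their direction in every alternative. All kept their side of the threshold with quantile normalization, a mean of 100 RPM, RLE, the filter at 1 read and, where they apply, removal of red cell miRNAs (85 calls) and shared barcodes (16 calls). The number that no longer passed was 17 with no filter, 8 with a pseudocount of 0.1, 6 with one of 10, 63 with a fit on the compared groups alone, 1 with TMM, 6 of 60 with mature entries alone, 18 with CLP counted as 1 library, 4 with edgeR and 4 with DESeq2. Depth limits CDP most, where 1 read was worth 8.79 RPM in CDP 1 and 23.5 RPM in CDP 2.

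The calls were 146 for splenic DC against progenitors, 0 for CMP against HSC, 5 for CLP against HSC, 0 for CLP against CMP, 10 for CDP against CMP, 70 for cDC against CDP, 81 for pDC against CDP, 0 for pDC against cDC, 67 for Flt3L cDC against cDC and 184 for miRNAs differing among the 7 groups. Of 495 ways to split the 12 splenic DC and progenitor libraries into 4 and 8, 100 were drawn, and 1 of them, the real one, gave as many calls as the real split in a fit of 2 means (109). The highest other count was 23. Only 15 of the 495 keep replicates together, so the result cannot be told apart from chance at the level of groups. The 15 splits by whole group, added after seeing the data, are too few for a share under 0.05 (real count 109, highest other 11). The lists called were 13, 7, 6, 3, 3, 10, 9, 7 and 5 for the first 9 of these comparisons in the same order.

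With an estimated correlation between miRNAs the lists called were 0 for splenic DC against progenitors, 1 for CMP against HSC and 0 for each of CLP against HSC, CLP against CMP, CDP against CMP, cDC against CDP, pDC against CDP, pDC against cDC and Flt3L cDC against cDC. For this and the following shifts the cause was not tested. Quantile normalization gave 15 calls for CLP against HSC, 2 for CLP against CMP, 24 for CDP against CMP and 7 lists for CDP against CMP. TMM gave 1 for CLP against CMP, 51 for CDP against CMP (with 7 lists), 132 for cDC against CDP and 165 for pDC against CDP. RLE gave 1, 25 (with 5 lists), 111 and 126 for the same comparisons, and 8 lists for Flt3L cDC against cDC. A pseudocount of 0.1 gave 3 calls for CLP against HSC and 25 for CDP against CMP. A pseudocount of 10 gave 14 for CLP against HSC, 5 for CLP against CMP and 7 lists for CDP against CMP.

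Among the filters, no filter gave 2 calls for CMP against HSC, 13 for CLP against HSC, 7 for CLP against CMP, 42 for pDC against CDP and 9 lists for Flt3L cDC against cDC. A mean of 100 RPM in 1 group gave 11 for CLP against HSC, 2 for CLP against CMP, 42 for cDC against CDP, 34 for Flt3L cDC against cDC and 109 over the 7 groups. It gave 1 list for CMP against HSC, 4 for pDC against cDC and 0 for Flt3L cDC against cDC. The filter at 1 read gave 8 calls for CLP against HSC. Mature entries alone gave 1 call for CDP against CMP, 44 for cDC against CDP, 37 for pDC against CDP, 42 for Flt3L cDC against cDC and 117 over the 7 groups. The lists called were then 4 for CMP against HSC, 1 for CLP against CMP, 3 for pDC against CDP, 4 for pDC against cDC and 2 for Flt3L cDC against cDC.

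A fit on the compared groups alone, with fewer libraries for the spread, gave 7 calls for CMP against HSC, 78 for CLP against HSC, 23 for CLP against CMP and 45 for CDP against CMP, and 0 for cDC against CDP, pDC against CDP and Flt3L cDC against cDC. CLP counted as 1 library gave 0 for CLP against HSC, 1 for CDP against CMP, 52 for pDC against CDP and 73 over the 7 groups. Within shared barcodes, pDC against Flt3L cDC in place of cDC gave 34. edgeR gave 9 for CLP against HSC. DESeq2 gave 11 for CMP against HSC, 24 for CLP against HSC, 21 for CLP against CMP, 40 for CDP against CMP, 21 for pDC against cDC, 110 for Flt3L cDC against cDC and 289 for miRNAs differing among the 7 groups. limma-voom was not run, because the deposited values were not raw counts, and DESeq2, planned for raw counts alone, was run on recovered reads instead.

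The replicate number as a block (replicate block) gave 9 calls for CLP against HSC, 27 for CDP against CMP, 106 for cDC against CDP and 6 lists for CDP against CMP. The numbers did not pair the libraries by the rule set, since 13 of 21 pairs of groups had a correlation of deviations over 0.1 (lowest -0.03, median 0.117, highest 0.318). As a hint from the data, 14 of 14 libraries correlated best with libraries of their own number, which amounts to 7 outcomes, since the deviations of the 2 libraries of a group mirror each other.

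Leaving out 1 library at a time, with the lone library of a group assumed to vary like the other groups, gave 107 to 186 calls for splenic DC against progenitors, 0 to 0 for CMP against HSC, 0 to 23 for CLP against HSC, 0 to 11 for CLP against CMP, 0 to 49 for CDP against CMP, 39 to 134 for cDC against CDP, 38 to 121 for pDC against CDP, 0 to 66 for pDC against cDC, 26 to 101 for Flt3L cDC against cDC and 72 to 290 over the 7 groups. Lists called ranged from 11 to 14, 5 to 8, 4 to 8, 3 to 5, 2 to 6, 7 to 11, 6 to 11, 1 to 9 and 3 to 8 for the first 9 in the same order.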

Other observations

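All values in this part were chosen after seeing the data, and none was tested here beyond the comparisons of the results. miR-223, a regulator of granulocytes, stood at 2942 ± 2174 RPM in HSC, 23557 ± 21058 in CMP, 5064 ± 402 in CLP, 1675 ± 1470.4 in CDP, 7212 ± 8114 in cDC, 7676 ± 9723 in pDC and 16121 ± 8269 in Flt3L cDC. miR-142-3p, found in all blood lineages, stood at 8088 ± 4059.6, 11208 ± 11062, 6669 ± 301, 3346 ± 2223, 27682 ± 10549, 25375 ± 28426 and 13139 ± 9064 RPM in the same order. miR-155, needed for normal function of DC and lymphocytes, stood at 4924 ± 2148, 4065 ± 3247, 3466 ± 49.2, 1895 ± 581, 1659.7 ± 499.9, 2126 ± 1359 and 8032 ± 71.2 RPM. miR-126-3p, shared by stem cells and endothelium, stood at 1453 ± 1115, 2274 ± 492, 11106 ± 443, 662 ± 328, 121 ± 65.6, 1969 ± 2545 and 998 ± 506 RPM.

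Red cell miRNAs summed to 235 ± 154 RPM in HSC, 97.1 ± 6.36 in CMP, 185 ± 5.78 in CLP, 212 ± 299 in CDP, 306 ± 91.6 in cDC, 267 ± 45.1 in pDC and 710.0 ± 238 in Flt3L cDC. The CLP libraries were the closest pair of any group, with a Pearson r of 0.965 across miRNAs and a median absolute log2 difference of 0.165.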
